A study of Homo sapiens with 12 samples.

How the data were processed

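RNA of H929 cells was extracted with Trizol, labelled with biotin by a 3' in vitro transcription kit and hybridised to arrays of 54675 probe sets, per the labels' protocols. The data are a single table of 12 arrays in 4 groups of 3, with the groups taken from the sample titles and treatments. Its values are log2 intensities deposited by the authors, background-corrected, normalized and summarized per probe set with RMA and the affy package, per the submitters' processing notes, which give no versions. In every array the values ran from about 2.2 to 14.9, and the quantiles of the arrays differed by at most 0.205, so the deposited values were used without further normalization. No array was a copy of another, with 17 to 90 of the 54675 deposited values exactly equal, at all digits given, in any pair. Arrays give no read depth, and their number limits the precision.

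Probe sets were named from the annotation table given for the platform. Of the probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 were not listed with a gene, and only those with 1 symbol were named. Gene IDs of 41043 were matched to a table of current human gene names from assembly GRCh38.p14, which changed 0 symbols, and no coordinates were used. The 19775 genes were each represented by the probe set with the highest mean over the 12 arrays. Genes were kept when that probe set lay above the 40th percentile of its array (a level of 4.86 to 4.95) in at least 3 arrays, which left 14725. Where the probe sets above that level of a gene named by the rule below differed in sign in a treatment comparison for which its value is given, the text says so.

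A linear model with a mean per group was fitted to all 12 arrays in limma 3.58.1 (lmFit and eBayes) under R 4.3.3, so that the groups shared an estimate of the spread. The contrasts were shBCL9 minus shGFP, miR-30 minus cel-miR-67, and the difference of these effects (miR-30 minus shBCL9). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and all adjusted p-values of genes are limma's. BCL9 and the RNA quality probe sets were also tested with exact permutation tests, two-sided, in which 3 against 3 arrays cannot give a p below 0.1. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

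The 28 gene lists were Wnt target genes, Wnt pathway components, G1/S and DNA replication, G2/M and mitosis, p53 target genes, pro-apoptotic genes, anti-apoptotic genes, adhesion and migration, plasma cell identity, ER chaperones and unfolded protein response, ATF4 target genes, interferon-stimulated genes, NF-kappaB target genes, immediate early genes, ribosomal proteins, ribosome biogenesis and MYC-linked growth, oxidative phosphorylation, hypoxia and glycolysis, cholesterol biosynthesis, proteasome subunits, autophagy genes, miR-30 literature targets, miRNA machinery, and markers of B cells, T and NK cells, myeloid cells, erythroid cells, and stromal and epithelial cells. Each was tested with limma's camera with a preset correlation of 0.01, adjusted over the 28 lists. Camera with an estimated correlation and fry, which does not compare a list with other genes, were run beside it. The designs, lists, alternatives and the rule for named genes were fixed before the data were examined. The text names BCL9 and, for each treatment, the 10 called genes with the largest rise and the 10 with the largest fall whose 3 treated arrays all lay on the same side of the 3 controls. It also names up to 4 called members of each list by adjusted p, members of the Wnt, miR-30 and anti-apoptotic lists given as not called, the 5 genes with the largest difference of effects each way, and up to 5 genes per direction called in both comparisons.

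The alternatives were no filter or a stricter one (60th percentile), the mean of a gene's probe sets, plain probe sets without shared or cross-hybridising suffixes, a further quantile normalization, centring of each array on its median, only the 6 arrays of a comparison, array weights, a variance model with trend and robust estimation, a replicate block, stricter thresholds (0.01, or 2-fold), camera on ranks, and leaving out each array in turn. Covariates for RNA quality (the ACTB 3' to 5' difference, the poly-A spike-in signal and the 18S rRNA signal of each array) were added after the data were seen. Regroupings used all 10 splits of 3 against 3 arrays within an arm, and 100 splits of both arms together.

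The pipeline was tested on simulated data of the hairpin and transfected arms, with 14725 genes. For single genes, the pipeline was tested on changes planted in the simulated comparison of shBCL9 with shGFP. It recovered 13 of 50 genes changed by 0.25 on the log2 scale, 45 of 50 changed by 0.5, and 50 of 50 changed by 1 or by 2, with 9 false calls. In a simulated miR-30 arm a list shifted by 0.25 was called, and 0 of 27 unshifted lists were. The simulated genes were drawn independently, so this does not test lists whose genes vary together. In the real arrays, splits that mixed the miR labels called up to 4 lists. Probe sets with several genes or none listed were left out of the comparisons of genes. A test of genes with miR-30 seed matches in their 3' untranslated regions was planned and not run, because sequences of these regions were not used here.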

Results

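Gene expression was measured on microarrays in H929, an established human cell line of multiple myeloma, a cancer of antibody-secreting plasma cells. The 12 arrays formed 4 groups of 3. In the infected arm, the cells carried a short hairpin RNA against green fluorescent protein (shGFP, the control) or against BCL9 (shBCL9), and fluorescent cells were collected by sorting. In the transfected arm, the cells received the worm microRNA cel-miR-67, which served as control, or human miR-30. The labels list miR-30 family members a to e without saying whether they were given together. Array medians lay between 5.46 and 5.53 on the log2 scale. Across genes, arrays of the same group correlated at r = 0.997 to 0.998, shBCL9 arrays with shGFP arrays at 0.989 to 0.992, and miR-30 arrays with cel-miR-67 arrays at 0.996 to 0.997. Nothing in the labels says that the arrays of a group came from separate cultures, so the p-values below measure only the spread between these arrays, which may be technical. The number of arrays, 3 per group, limits the precision of every value.

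The first question was whether BCL9, a co-activator of beta-catenin in Wnt signalling, was lower in the treated cells, because the hairpin was directed against it and the title of the series names it as the target of miR-30-5p. BCL9, measured by a single probe set, read 7.88 ± 0.01 (SD, n = 3) in shGFP and 7.73 ± 0.12 (SD, n = 3) in shBCL9, a log2 difference of -0.15 ± 0.07 (SE). All 3 shBCL9 arrays lay below all 3 shGFP arrays. This corresponds to a change of -10.1% (95% interval -18.9% to -0.443%), and it did not pass the threshold in limma over all genes (adjusted p = 0.0874). The exact permutation test gave p = 0.1 (two-sided), the smallest that 3 against 3 arrays allow. Without shBCL9 replicate 3 the difference was -0.21 and was called (adjusted p = 0.031), and it was also called with array weights (-0.17, adjusted p = 0.0261), within a range of 0.0261 to 0.426 over the alternatives. After a further quantile normalization it was -0.075 (adjusted p = 0.426). In the transfected arm BCL9 measured 7.82 ± 0.04 (SD, n = 3) with cel-miR-67 and 7.96 ± 0.11 (SD, n = 3) in the arrays labelled miR-30, a difference of 0.14 (95% interval -0.0083 to 0.29). The arrays overlapped, and neither limma (adjusted p = 0.269) nor the exact permutation test (p = 0.2, two-sided) called it. The direction was opposite to a fall of BCL9 RNA, but the change was not called. In percent the 95% interval ran from -0.574% to 22.1%, so it held almost no fall of BCL9 RNA at this probe set. The arrays do not read BCL9 protein, so these values leave the title of the series open at that level. As no fall of BCL9 RNA was seen, the transfected group is described below as the arrays labelled miR-30. The BCL9 effects of the arms differed by 0.29 (adjusted p = 0.0404 in limma).

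**Figure D1:**
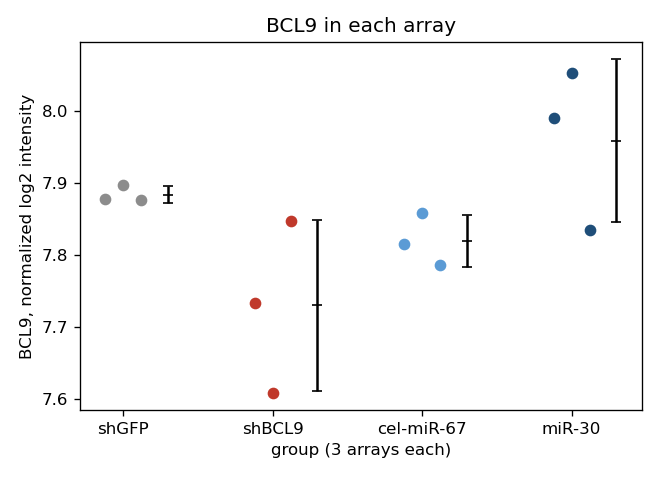
BCL9 level (normalized log2 intensity, vertical axis) in each of the 12 arrays by group (horizontal axis), with 1 dot per array and a bar at each side for the mean and 1 SD of 3 arrays. The shBCL9 arrays lie between 7.61 and 7.85, below the shGFP arrays (7.88 to 7.90), and the arrays labelled miR-30 lie between 7.84 and 8.05 against 7.79 to 7.86 for cel-miR-67.

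By the brightest probe set of each gene, the shBCL9 cells differed from the shGFP cells most in CCND2, which encodes a D-type cyclin of the G1 phase. CCND2 fell by 4.60 on the log2 scale, from 10.70 ± 0.03 to 6.10 ± 0.17 (SD, n = 3 each), a 24.2-fold difference (adjusted p = 8.95e-13), and the mean of its 4 probe sets, all lower, changed by -2.38, less than that of MACROD2 (-3.76). MACROD2, which encodes an ADP-ribose hydrolase, was 14.6-fold lower, and ZFP36L1, which encodes an RNA-binding protein that promotes mRNA decay, was 13.5-fold lower. The antisense RNA TMEM132D-AS1 (-4.20), POPDC3 (-3.31), the cytokine receptor gene IL23R (-2.94), the T cell receptor beta constant gene TRBC1 (-2.89), ARMCX1 (-2.83), BHLHE41 (-2.71) and the cancer-testis antigen gene PAGE1 (-2.62) also fell. FAM43A rose most by its brightest probe set, by 3.27 on the log2 scale (SE 0.09, 9.67-fold), from 6.84 ± 0.22 to 10.11 ± 0.06 (SD, n = 3 each). The growth factor gene HBEGF rose 8.25-fold, CRIP1 6.70-fold and the interferon-induced gene IFI27 6.06-fold. PRSS2 (5.66-fold), FBXL13 (2.40), NFE4 (2.26), the transcription factor gene SOX4 (2.24), ADGRE2 (2.15) and the interferon-induced gene IFITM1 (2.10) completed the 10 largest rises. As the mean of their probe sets, FAM43A rose by 1.92, HBEGF by 1.86, PRSS2 by 1.88 and SOX4 by 1.09, below CRIP1 and IFI27, which have 1 probe set each. By the rule that named these genes, all 3 treated arrays of each lay on the same side of all 3 controls. In shBCL9, ZFP36L1 (3.36), POPDC3 (3.78), TMEM132D-AS1 (4.11), IL23R (4.67), PAGE1 (4.82) and BHLHE41 (4.86) lay under the filter level of 4.95, and in shGFP, FBXL13 (4.62), PRSS2 (4.79) and ADGRE2 (4.87) lay under 4.91, so the sizes of these changes and their order rest on values near background.

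In limma, 6118 of 14725 genes (41.5%) passed an adjusted p of 0.05 between shBCL9 and shGFP, 2749 higher (44.9%) and 3369 lower. After a further quantile normalization 3274 of 6248 were higher (52.4%), and with arrays centred on their medians 2132 of 5802 (36.7%), so the balance of directions depended on the scaling. Of the main calls, 280 changed at least 2-fold, 68 higher and 212 lower. The arrays of the groups did not overlap in 7664 genes (52%), where chance gives 10%. Signs of RNA quality and labelling moved with the hairpin. The difference between 3' and 5' control probe sets of ACTB was 1.67 ± 0.08 in shBCL9 and 1.30 ± 0.11 in shGFP (SD, n = 3 each; exact permutation p = 0.1, two-sided), that of GAPDH 0.131 ± 0.021 and 0.136 ± 0.019 (exact permutation p = 0.5), and the 18S rRNA probe sets read 13.23 ± 0.02 and 12.38 ± 0.07. The hybridisation spike-ins read 10.71 ± 0.05 in shBCL9 and 10.99 ± 0.12 in shGFP (SD, n = 3 each; exact permutation p = 0.1, two-sided). With the ACTB difference of each array as a covariate, 2968 genes were called, with the poly-A spike-in signal 2789 and with the 18S signal 11, all added after the data were seen. The fitted changes did not shrink with the ACTB covariate (median ratio 1.196 for changes under 2-fold and 1.08 for larger ones), while the median standard error of the changes under 2-fold rose from 0.066 to 0.144. These medians cover all called genes of each size, not only those that lost their call, and why calls were lost was not tested. With the 18S covariate the median ratio for changes of 2-fold and more was 1.1 and their median standard error rose from 0.085 to 0.622.

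Among the gene lists, the immediate early genes, which growth factor signals induce within minutes, fell as a group in shBCL9. Of 16 measured, 9 fell, including FOS (-2.56), KLF2 (-1.42), JUN (-1.17) and DUSP1 (-0.95), and 1 rose (camera adjusted p = 0.00331; adjusted p = 0.0952 with an estimated correlation). Another probe set of JUN measured 0.02, and 1 of DUSP1 differed in sign, so that the means of probe sets were -0.66 for JUN and -0.24 for DUSP1. KLF2 measured -0.19 (adjusted p = 0.145) with plain probe sets only, and FOS lay near background in shBCL9 (4.85). The targets of ATF4, a transcription factor of the amino acid stress response, rose. Of 24 measured, 18 rose, including ATF3 (0.94) and the cystine transporter gene SLC7A11 (0.83), while DDIT4 (-0.81) and VLDLR (-0.79) fell (camera adjusted p = 0.00331; adjusted p = 0.199 with an estimated correlation). The interferon-stimulated genes rose as a list, with 10 of 23 higher, including IFI27, MX1 (1.79, 3.45-fold) and MX2 (1.67), and 3 lower, including SAMD9 (-1.64). The camera adjusted p was 0.0131, and the adjusted p was 0.174 with an estimated correlation. Genes of the miRNA machinery fell, with 8 of 18 lower and 1 higher (camera adjusted p = 0.0131; adjusted p = 0.319 with an estimated correlation). TNRC6C (-1.42), AGO4 (-1.15), PAN2 (-0.74) and AGO1 (-0.67) were among them, and other probe sets of TNRC6C, AGO4 and AGO1 differed in sign, with means of probe sets of -0.23, -0.42 and -0.22. The miRNA machinery list was not called with the mean of probe sets (adjusted p = 0.0917), nor the interferon list with camera on ranks (adjusted p = 0.0511). Adjusted over the list alone, 2 immediate early genes rose and 9 fell, 18 ATF4 targets rose and 2 fell, 12 interferon-stimulated genes rose and 3 fell, and 1 gene of the miRNA machinery rose and 8 fell.

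Growth and sterol genes rose by smaller amounts in shBCL9. In ribosome biogenesis and MYC-linked growth, 9 of 21 rose and none fell, including SRM (0.26), FBL (0.25), UTP20 (0.20) and DDX21 (0.19), with a camera adjusted p of 0.0131 (adjusted p = 0.128 with an estimated correlation). In cholesterol biosynthesis, 9 of 15 rose, including DHCR7 (0.50), MVD (0.50) and the regulator gene SREBF2 (0.36), and MSMO1 (-0.33) fell, with the same adjusted p-values. In G1/S and DNA replication, 10 of 26 rose, including MCM10 (0.43), GINS1 (0.41) and TK1 (0.32), and 2 fell, including CCNE2 (-0.55), with a camera adjusted p of 0.0201 (adjusted p = 0.319 with an estimated correlation). Adjusted over the list alone, 12 G1/S genes rose and 2 fell, 10 cholesterol genes rose and 1 fell, and 9 ribosome biogenesis genes and 5 stromal and epithelial markers rose. MCM10 was not called with plain probe sets (0.17, adjusted p = 0.0963). Stromal and epithelial markers, fixed as signs of other cells, rose in 5 of 12 genes, KRT18 (0.50), COL6A1 (0.40), MUC1 (0.32) and CLDN4 (0.28) among them, with a camera adjusted p of 0.0216 (adjusted p = 0.142 with an estimated correlation). CLDN4 lost its call in 2 of 15 alternatives (adjusted p up to 0.0716), and COL6A1 was 0.22 as the mean of probe sets. No list of the 28 was called in this comparison with an estimated correlation, and the ACTB 3' to 5' difference was higher by 0.378 in the same shBCL9 arrays in which these 8 lists moved.

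Wnt target genes changed in both directions in shBCL9. Of 24 measured, 5 rose and 8 fell, and the same numbers passed adjusted over the list alone. CCND2, SNAI2 (-1.73, near background in shBCL9 at 3.83) and JUN fell, whereas the cyclin gene CCND1 rose (1.10, SE 0.06). MYC (-0.34) and the Wnt inhibitor gene DKK1 (1.25), chosen after their values were seen, also passed, and AXIN2, a feedback target of beta-catenin, measured -0.02 (adjusted p = 0.872). The list's median was -0.006 and its mean -0.24, and camera did not call it (adjusted p = 0.523). In fry, which asks only whether the list's genes move one way on balance, the adjusted p was 2.37e-06 (lower). Wnt pathway components had 7 of 28 higher and 8 lower (camera adjusted p = 0.96). TLE1 (-0.58), BTRC (-0.44), TLE3 (-0.36) and CTBP1 (-0.26) fell, and with plain probe sets BTRC (0.20, adjusted p = 0.0915) and CTBP1 (0.041, adjusted p = 0.759) turned in sign and were not called.

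The anti-apoptotic list had 3 of 9 genes lower, CFLAR (-0.91), MCL1 (-0.43) and BIRC2 (-0.15), and BCL2 higher (0.38), with probe sets of BCL2 in disagreement (camera adjusted p = 0.454). BCL2 was not called as the mean of its probe sets (0.14, adjusted p = 0.0787), and BIRC2 lost its call in 3 of 16 alternatives (up to 0.058). The pro-apoptotic list had 6 of 18 higher, including PMAIP1 (0.54) and BAK1 (0.38), and 7 lower, including the death ligand gene TNFSF10 (-0.95, near background in shBCL9 at 4.21) and BCL2L11 (-0.54; other probe sets differed in sign, mean -0.23), with a camera adjusted p of 0.724. Among p53 targets, 9 of 21 rose, including the cell cycle inhibitor gene CDKN1A (0.61), and 4 fell, including TP53INP1 (-1.81; another probe set differed in sign, mean -0.82), with a camera adjusted p of 0.437. G2/M and mitosis genes had 5 of 26 higher and 4 lower (camera adjusted p = 0.481), with KIF20A and BUB1B up and TOP2A and BUB1 down, and with probe sets of BUB1 in disagreement. Adhesion and migration genes had 6 of 28 higher and 5 lower (camera adjusted p = 0.96), with S100A4 (-1.52) and ICAM1 (0.68) as the strongest changes. The plasma cell identity list had 5 of 19 higher and 5 lower (median -0.026, camera adjusted p = 0.805). Its surface markers SDC1 (0.88) and CD38 (0.71) and the gene ITM2C (0.91) rose, and SEL1L3 (-0.94) fell.

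The other lists were not called between shBCL9 and shGFP. Autophagy genes had 10 of 23 lower, including SQSTM1 (-0.66; another probe set differed in sign, mean -0.24) and MAP1LC3B (-0.59), and 2 higher (camera adjusted p = 0.0601). The miR-30 literature targets had 10 of 25 lower, including IRS2 (-1.03), and 1 higher (camera adjusted p = 0.0752). With the mean of probe sets both lists were called (adjusted p = 0.0103 each), as they were with no filter (0.0256 for autophagy and 0.0247 for the miR-30 targets). Hypoxia and glycolysis genes had 3 of 23 higher and 9 lower (adjusted p = 0.454), with ENO2 at -1.66. ER chaperones had 3 of 19 higher and 5 lower (adjusted p = 0.454), with HSPA5 (-0.77) and DNAJB9 (-0.93) down. NF-kappaB targets had 2 of 16 higher and 5 lower (adjusted p = 0.481), with CCL4 at -1.58. Oxidative phosphorylation genes had 5 of 25 higher and 3 lower (adjusted p = 0.562), proteasome subunits 4 of 22 higher and none lower (adjusted p = 0.152), and none of 22 ribosomal proteins was called (adjusted p = 0.805). Among markers of other blood cells, 1 of 12 B cell markers was higher and 3 lower, with HLA-DPA1 at -1.01 (near background in shBCL9 at 4.35) and BACH2 at -0.55 (adjusted p = 0.706), 1 of 9 T and NK cell markers was higher and 3 lower, with the granule protein genes GZMB at -1.34 and PRF1 at -0.63 (adjusted p = 0.6), 1 of 4 myeloid markers was higher (adjusted p = 0.481) and 1 of 9 erythroid markers was higher (adjusted p = 0.152). As means of probe sets, which differed in sign for PRF1, PRF1 was -0.31 and BACH2 -0.87. In 6 lists that were not called here, and in 8 in the arrays labelled miR-30, the signs of the median, the mean and the test were not all the same.

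**Figure D2:**
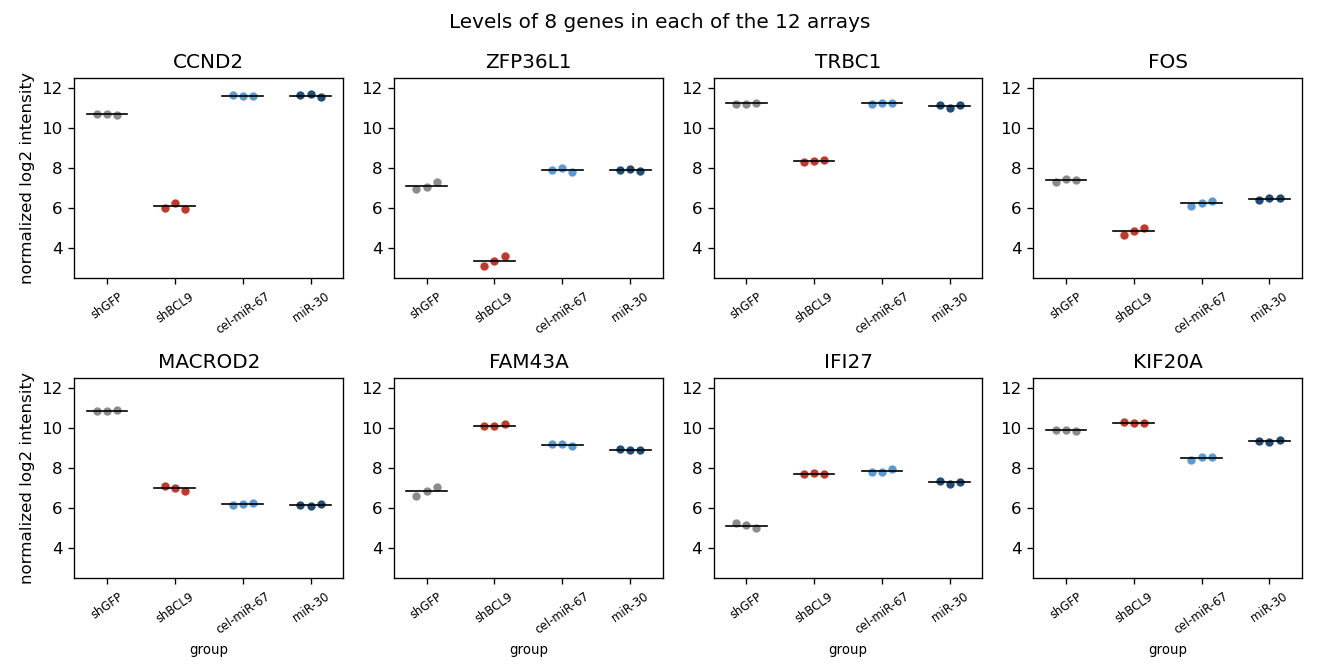
Normalized log2 intensity (vertical axis) of 8 genes in each of the 12 arrays, with 1 dot per array, the 4 groups on the horizontal axis and a line at each group mean. CCND2, ZFP36L1 and TRBC1 are lowest in shBCL9, MACROD2 is highest in shGFP at 10.87, and KIF20A is higher in the arrays labelled miR-30 (9.36) than with cel-miR-67 (8.52).

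In the arrays labelled miR-30, genes of cell division rose and interferon-stimulated genes fell relative to the cel-miR-67 arrays. E2F8, which encodes a transcription factor of the E2F family, rose most by the brightest probe sets, from 7.58 ± 0.10 to 8.50 ± 0.09 (SD, n = 3 each), a log2 change of 0.92 (SE 0.07, 1.89-fold, adjusted p = 3.38e-05). The mitotic kinesin genes KIF20A (0.84), KIF14 (0.74) and KIF23 (0.72, and 1.10 with plain probe sets) rose, as did GAS2L3 (0.83), ARHGAP11A (0.77), CDC25C (0.73), which encodes a phosphatase that activates CDK1, MYB (0.71), LINC00597 (0.69) and FAM83D (0.69). SPRR2C fell most, by 0.77 on the log2 scale (adjusted p = 0.0158). The interferon-induced genes IFIT1 (-0.66), XAF1 (-0.61) and IFI27 (-0.55) fell, as did CSTA (-0.65), ADCY1 (-0.63), AOC3 (-0.62), CAV2 (-0.59), NRSN2-AS1 (-0.55) and the drug efflux pump gene ABCB1 (-0.54). Another probe set of ADCY1 measured 0.10, and their mean was -0.27. When arrays of this arm were left out in turn, the adjusted p reached 0.134 for XAF1, 0.132 for CAV2, 0.088 for NRSN2-AS1, 0.0817 for ABCB1 and 0.0717 for SPRR2C. In these arrays ABCB1 (4.62) and NRSN2-AS1 (4.83) lay under the filter level of 4.90.

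In limma, 734 of 14725 genes (4.98%) passed between these groups, 346 higher and 388 lower. With a further quantile normalization 775 passed, 452 of them higher (58.3% against 47.1%), and with arrays centred on their medians 268 of 660 (40.6%). No called gene changed 2-fold, while 3091 genes had an unadjusted p under 0.05 in limma. The groups did not overlap in 3843 genes (26.1%), where chance gives 10%. The ACTB 3' to 5' difference was 2.07 ± 0.01 in the arrays labelled miR-30 and 2.16 ± 0.09 with cel-miR-67 (SD, n = 3 each; exact permutation p = 0.4, two-sided), and that of GAPDH differed by 0.024 (exact permutation p = 0.6). The 18S rRNA probe sets were higher by 0.136 (exact permutation p = 0.1, the smallest possible) and the poly-A spike-ins lower (-0.155, exact permutation p = 0.2). With the 18S signal as a covariate, added after the data were seen, 56 genes were called. The count of calls fell whichever array of this arm was left out, and why was not tested. It was 413, 297 and 386 without cel-miR-67 replicates 1, 2 and 3. Without miR-30 replicates 1, 2 and 3 it was 527, 315 and 542. Over the variance models, probe set choices, filters and array sets tried, it ranged from 443 to 1419.

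The G2/M and mitosis list rose almost as a whole in the arrays labelled miR-30. Of 26 genes, 25 rose and 1, CDK1 (0.12, adjusted p = 0.372), did not pass. The median change was 0.45, with CDC20, which activates the anaphase-promoting complex, at 0.63 and the spindle checkpoint kinase gene BUB1B at 0.52 (camera adjusted p = 1.18e-43; adjusted p = 0.000736 with an estimated correlation). G1/S and DNA replication genes rose as well, 13 of 26 over all genes and 18 adjusted over the list alone, including CCNE1 (0.33) and the replicative helicase genes MCM6 (0.34) and MCM3 (0.25). The camera adjusted p was 1.43e-16, and the adjusted p was 0.00641 with an estimated correlation. Interferon-stimulated genes fell in 7 of 23 cases over all genes and in 13 adjusted over the list alone, including MX1 (-0.45) and the transcription factor gene IRF9 (-0.34), with a camera adjusted p of 1.96e-06 (adjusted p = 0.0224 with an estimated correlation). Adjusted over the list alone, 25 G2/M genes rose, and so did 5 immediate early genes. Immediate early genes rose in 5 of 16 cases, including EGR1 (0.58), JUN (0.38), KLF2 (0.32; 0.03 with plain probe sets only, adjusted p = 0.912) and MAFF (0.25; another probe set measured -0.01, mean 0.12 with adjusted p = 0.192), with a camera adjusted p of 0.000806 (adjusted p = 0.0229 with an estimated correlation).

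Autophagy genes had a median of -0.10 in the arrays labelled miR-30, with SQSTM1 (-0.25; another probe set measured 0.19) as the only one of 23 called (camera adjusted p = 0.00685; adjusted p = 0.245 with an estimated correlation). Proteasome subunits had a median of -0.06, with PSMB5 (-0.24) as the only one of 22 called (camera adjusted p = 0.0413; adjusted p = 0.757 with an estimated correlation). Among p53 targets, CDKN1A (-0.29), ZMAT3 (-0.30), TP53INP1 (-0.23; another probe set measured 0.03) and 1 more of 21 fell and CCNG1 rose (0.24), with a camera adjusted p of 0.0473 (adjusted p = 0.319 with an estimated correlation). The call of the p53 list was lost without cel-miR-67 replicate 2 (0.0995) or 3 (0.0855) and without miR-30 replicate 2 (0.1) or 3 (0.0518), and that of the proteasome list without cel-miR-67 replicate 3 (0.243) or miR-30 replicate 2 (0.225) and with only the 6 arrays of the arm (0.0883). TP53INP1 lost its call in 9 of 16 alternatives (adjusted p up to 0.363), SQSTM1 in 7 of 16 (up to 0.988), CCNG1 in 4 of 15 (up to 0.0583), ZMAT3 in 4 of 16 (up to 0.0731), PSMB5 in 4 of 16 (up to 0.0858) and CDKN1A in 2 of 15 (up to 0.0563). Both calls were also lost after quantile normalization (0.0663 for p53 targets and 0.106 for the proteasome). Adjusted over the list alone, 3 autophagy genes, 3 proteasome subunits and 5 p53 targets fell, and 1 p53 target rose.

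Wnt target genes had 3 of 24 higher in the arrays labelled miR-30, JUN, BIRC5 (0.34) and LEF1 (0.22; another probe set measured -0.03), and CCND1 lower (-0.28), with a camera adjusted p of 0.158. Adjusted over the list alone, 4 rose and 1 fell. CCND2 measured 0.02 (adjusted p = 0.912; its probe sets ran from -0.153 to 0.02), AXIN2 0.26 (adjusted p = 0.18), and none of 28 Wnt pathway components was called (camera adjusted p = 0.383). Among the miR-30 literature targets, a list of genes described elsewhere as targets, 1 of 25 rose (CCNE2, 0.41) and 1 fell (NT5E, -0.30; another probe set differed in sign). Their median was 0.012, and camera did not call the list (adjusted p = 0.43). SNAI1 (0.05), BECN1 (-0.10) and PRDM1 (-0.01) were not called. In the anti-apoptotic list BIRC5 was the only one of 9 called (camera adjusted p = 0.643), and in the pro-apoptotic list BAD (-0.22) was the only one of 18 (camera adjusted p = 0.175). BIRC5 kept its call in all 16 alternatives, whereas LEF1 lost its call in 9 of 15 alternatives (adjusted p up to 0.173), BAD in 10 of 16 (up to 0.126), CCND1 in 5 of 16 (up to 0.106), JUN in 4 of 15 (up to 0.0679), CCNE2 in 4 of 16 (up to 0.0679) and NT5E in 11 of 16 (up to 0.733, with a value of -0.043).

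The remaining lists were not called in the arrays labelled miR-30, and probe sets of ATF5 and NOP16 differed in sign. Under the alternatives, camera called oxidative phosphorylation in 2 of 13 (adjusted p down to 0.0229) and ER chaperones in 1 of 13 (0.039). Plasma cell identity had 1 of 19 higher and 2 lower, with CD38 at -0.29 (adjusted p = 0.814). Adhesion and migration had CCR1 lower (-0.39) of 28 (adjusted p = 0.885), ER chaperones DNAJB9 lower (-0.21) of 19 (adjusted p = 0.161) and ATF4 targets ATF5 lower (-0.19) of 24 (adjusted p = 0.387). Ribosome biogenesis had SRM higher and NOP16 lower of 21 (adjusted p = 0.161), hypoxia and glycolysis PDK1 higher and BNIP3 lower of 23 (adjusted p = 0.161), and cholesterol biosynthesis STARD4 higher and HMGCS1 lower of 15 (adjusted p = 0.43). The calls were lost in 12 of 16 alternatives for HMGCS1 (adjusted p up to 0.169), 11 of 16 for DNAJB9 (0.14), 10 of 15 for ATF5 (0.285), 10 of 16 for NOP16 (0.529), 8 of 16 for SRM (0.0889), 6 of 15 for BACH2 (0.0986), 5 of 16 for PDK1 (0.11) and 2 of 16 for STARD4 (0.0563). BACH2 (0.32) was the only B cell marker called of 12 (adjusted p = 0.994). No member was called of NF-kappaB targets (adjusted p = 0.952), ribosomal proteins (0.994), oxidative phosphorylation (0.228), miRNA machinery (0.885), T and NK cell markers (0.886), myeloid markers (0.952), erythroid markers (0.885) or stromal and epithelial markers (0.952).

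**Figure D3:**
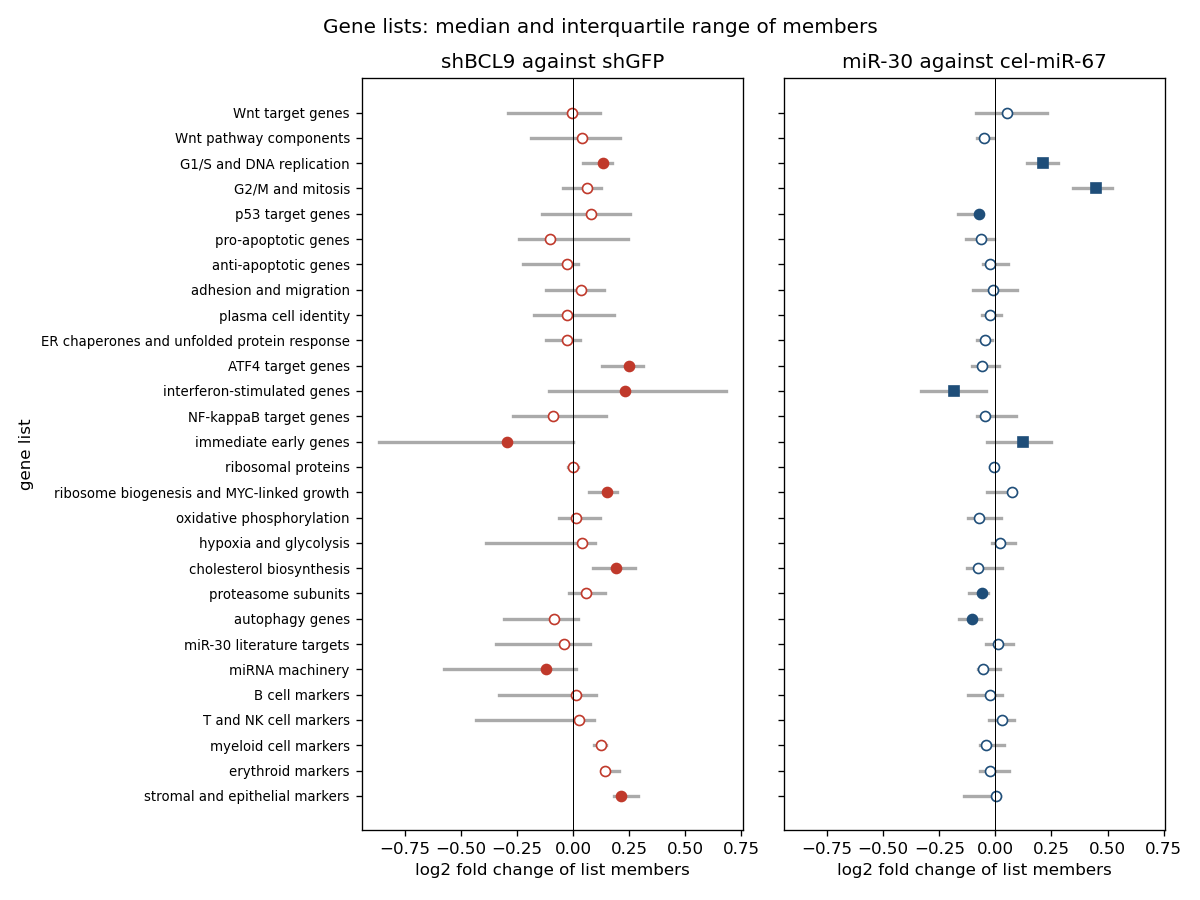
Median log2 fold change (dot) and interquartile range (bar) of the members of each of 28 gene lists, for shBCL9 against shGFP and for miR-30 against cel-miR-67 (horizontal axes). Filled symbols are lists called by camera, squares those called also with an estimated correlation, and open symbols those not called, with G2/M and mitosis at 0.45 in the miR-30 panel.

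The last question was whether the hairpin and the microRNA changed the same genes. Of the called genes, 280 changed at least 2-fold in shBCL9 and 0 in the arrays labelled miR-30. The miR-30 effect was higher by most in CCND2, TMEM132D-AS1, MACROD2, ZFP36L1 and POPDC3 (differences of 4.62 to 3.37). It was lower by most in FAM43A, IFI27, HBEGF, CRIP1 and PRSS2 (-3.53 to -2.64). As means of probe sets the differences were 2.28 for CCND2, -2.08 for FAM43A, -1.80 for HBEGF and -1.82 for PRSS2, so sizes and order depended on the probe set. Limma called the difference of the effects in 3872 genes, 2145 higher and 1727 lower in the miR-30 effect (2090 of 4110 higher after a further quantile normalization). With the ACTB covariate 1717 genes were called and with the 18S covariate 19, both added after the data were seen. The lists that differed were G2/M and mitosis (22 of 26 members higher in the miR-30 effect), immediate early genes (8 of 16 higher) and miRNA machinery (7 of 18 higher), against interferon-stimulated genes (13 of 23 lower and 1 higher), ATF4 targets (12 of 24 lower and 2 higher), cholesterol biosynthesis (7 of 15 lower) and proteasome subunits (6 of 22 lower). Adjusted over the list alone, 24 G2/M genes were higher, 10 immediate early genes higher and 1 lower, 7 miRNA machinery genes higher, 13 interferon-stimulated genes lower and 2 higher, 17 ATF4 targets lower and 2 higher, 8 cholesterol genes lower and 1 higher, and 9 proteasome subunits lower and 1 higher. With an estimated correlation, G2/M (adjusted p = 0.0304), interferon-stimulated (adjusted p = 0.0348) and immediate early genes (adjusted p = 0.018) were called, and the other 4 lists had adjusted p = 0.18 for ATF4 targets, 0.0607 for cholesterol biosynthesis, 0.581 for proteasome subunits and 0.323 for miRNA machinery.

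Of the genes called in both comparisons, 407 in all, 274 moved the same way and 133 opposite ways. Both comparisons raised 96 genes, including MYB (0.85 and 0.71), ARID5B (0.72 and 0.59) and E2F7 (1.00 and 0.68; another probe set showed no rise, means 0.50 and 0.33), where independent lists of these sizes would share 64.6. Both lowered 178, including CAV2 (-0.56, near background in both infected groups, and -0.59), CARD16 (-0.82 and -0.54) and the histone gene H4C8 (-1.14 and -0.52), against 88.8 for independent lists. In 54 genes shBCL9 was higher and the arrays labelled miR-30 lower (72.4 for independent lists), including IFIT1 (1.09 and -0.66), IFI27 (2.60 and -0.55) and MX1 (1.79 and -0.45). In 79 genes shBCL9 was lower and the arrays labelled miR-30 higher (79.2 for independent lists), including CKAP2L (-0.69 and 0.66), the transporter gene ABCG2 (-0.87 and 0.63) and EGR1 (-0.84 and 0.58). The ABCG2 call in the arrays labelled miR-30 was lost in 6 of 16 alternatives (adjusted p up to 0.0821) and that of CAV2 in 7 of 14 (up to 0.132). The comparisons share an estimate of the spread of each gene, so the counts for independent lists are not a chance level. In both treated groups the 18S rRNA probe sets were higher (0.85 and 0.136) and the poly-A spike-ins lower (-0.648 and -0.155). Whether this lies behind the shared directions was not tested. Across the 14725 genes, which are not independent replicates, the log2 changes correlated at r = 0.132 (Spearman's rho = 0.175). The count of 407 fell to 231, 156 and 217 without cel-miR-67 replicates 1, 2 and 3 and to 167 without miR-30 replicate 2. The arms also differed in how the RNA was delivered, so the delivery and the perturbation changed together.

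**Figure D4:**
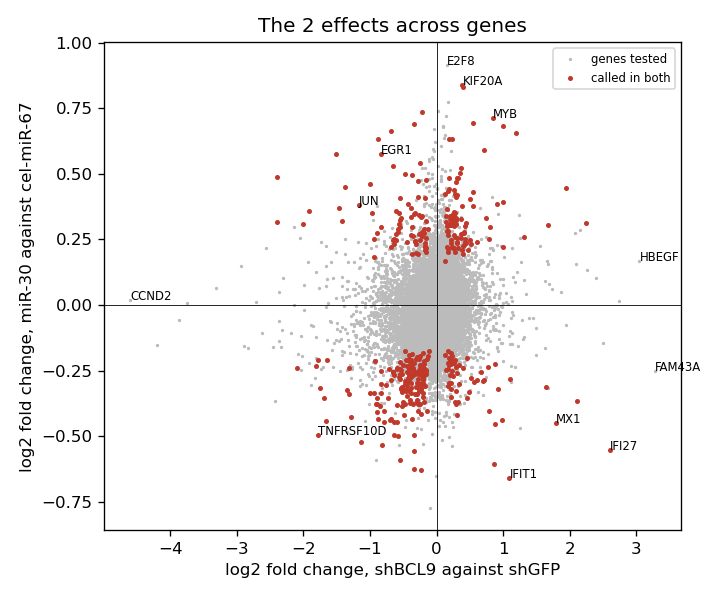
Log2 fold change of each of 14725 genes in shBCL9 against shGFP (horizontal axis) and in miR-30 against cel-miR-67 (vertical axis), with the 407 genes called in both in red. CCND2 lies at -4.60 and 0.02 (the brightest of 4 probe sets, which differ in sign on the vertical axis), IFI27 at 2.60 and -0.55 and E2F8 at 0.16 and 0.92.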

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

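The regroupings of arrays were fixed before the data were examined, and the tests with RNA quality covariates, signal-matched random lists, the nearer group of the other arm and the gene families were chosen after results were seen.

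The effects of the arms differed in 3872 genes, which is unusual because the title presents the perturbations as acting on the same gene. The interferon-stimulated list differed by a median of -0.386 and the immediate early list by 0.355, with medians of opposite sign in the arms, although in shBCL9 neither list was called with an estimated correlation (adjusted p = 0.174 and 0.0952). The BCL9 effect differed by 0.29 (adjusted p = 0.0404 in limma). BCL9 read lower with the hairpin and higher in the arrays labelled miR-30, but neither change was called (adjusted p = 0.0874 and 0.269 in limma). Control probe sets that no comparison of genes used also differed. In shBCL9 those of 18S rRNA were higher by 0.85 and the ACTB 3' to 5' difference was higher by 0.378. The poly-A spike-ins (-0.648) and the hybridisation spike-ins (-0.274) were lower, although spike-ins are meant to stay level. Among probe sets with no single gene, 1851 of 6603 (28%) were called with the hairpin and 49 (0.742%) in the arrays labelled miR-30, which the counts of genes leave out.

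Cell division genes were higher in the arrays labelled miR-30 while BCL9 and the miR-30 literature targets were not lower. An exchange of labels in this arm was not settled, because the literature targets had a camera p of 0.261 and so moved neither way. A trend with signal level was argued against, since the G2/M median lay at percentile 100 of 10000 signal-matched random lists (-0.125 to 0.0653). RNA quality as read by ACTB did not separate these groups, so a fit with that covariate could change little and decides nothing more. It gave a camera p (estimated correlation) of 3.42e-05 and a G2/M median of 0.455. With the 18S signal, which did separate these groups, the camera p was 0.000146 (median 0.417 against 0.449 without a covariate). There 8 members stayed called as the median standard error rose from 0.0572 to 0.0916. The 18S covariate follows the groups, so this fit cannot decide on ribosomal RNA or labelling. It stays open whether the labels, the microRNA or the state of the cells in these cultures lies behind the rise, and the pattern is a hypothesis found and tested on the same data.

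The hairpin arm had 6118 called genes with a BCL9 change of only -10.1%. With the ACTB covariate 2215 of 5838 changes under 2-fold stayed called. Over all 5838 the median ratio of fitted changes was 1.196, and the median standard error rose from 0.066 to 0.144. These medians do not single out the genes that lost their call, and why calls were lost was not tested. RNA quality cannot be told apart from the hairpin for these genes, because the covariate follows the groups. Of the changes of at least 2-fold, 273 of 280 stayed called with the ACTB covariate and 9 with the 18S signal (median ratio 1.1, median standard error 0.085 to 0.622). Larger changes can stay called at a lower precision, and both covariates follow the groups. For these genes too, RNA quality, ribosomal RNA and labelling stay open. For genes lowered 2-fold, dilution by cells other than plasma cells was argued against by the plasma cell list (median -0.0263, SD of members 0.505, where dilution needs -1 or lower). That list cannot tell another population of plasma cells apart. For raised genes the question of other cells stays open (stromal and epithelial median 0.214, camera adjusted p = 0.142 with an estimated correlation), although the cells were of an established line and sorted for fluorescence. A drift of the shGFP population could not be excluded, since 48 of these 280 genes lay within 0.5 of shBCL9 and more than 1 from shGFP in the cel-miR-67 arrays, and 60 lay the other way round, and how much of the contrast came from BCL9 itself stays open.

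Interferon-stimulated genes were lower in the arrays labelled miR-30 and higher with the hairpin, where the list's call was lost with an estimated correlation (adjusted p = 0.174) and with camera on ranks (0.0511). The median difference lay at percentile 0 of random lists of matched signal (-0.273 to 0.267), which argues against a trend with signal level. The pattern is a hypothesis found and tested on the same data. Camera with an estimated correlation gave p = 0.00373 for the difference (adjusted p = 0.0348 over the lists). That correlation comes from arrays of the same group, which may be technical repeats. It therefore cannot decide on genes that vary together between cultures. The same test gave 0.0141 with the ACTB covariate (median difference -0.541) and 0.00717 with the 18S signal (-0.647, with a median standard error per gene of 0.488). Both covariates follow the hairpin groups, so these fits cannot tell RNA quality or labelling apart from the hairpin. The arms differed in delivery, so it stays open whether viral infection, transfection or the target of each RNA may account for these changes.

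Within an arm the 10 splits are too few for a share under 0.05. The labelled split gave 6118 genes in the hairpin arm (highest other 0) and 734 in the transfected arm (highest other 0), and 8 and 7 lists (highest others 2 and 4), so it was 1 of 10 each time. For the difference of effects, 2 of 100 splits reached 3872 genes, a share of 0.02, and the other was the split with the miR labels exchanged (5016). Splits that kept the hairpin labels and mixed the miR labels gave 2775 to 3656 genes, and those that mixed the hairpin labels and kept or exchanged the miR labels 2 to 13, so most of this count follows the hairpin arm and says little about the miR labels. For the correlation of effects, 10 of 100 splits were as large as 0.132 (highest other 0.196), so regroupings gave values as large. For the genes called in both comparisons, 2 of 100 splits reached 407, and the other was again the exchanged one. A split that mixed the labels of an arm called 0 genes in that arm, so its count in both was 0 whatever the overlap. These splits therefore cannot show whether the effects share genes.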

How the results depend on the processing

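The limits were 3 arrays per group, 1 cell line, 1 hairpin and different delivery in the arms, and where a value moved the cause was not tested. For shBCL9 against shGFP, 280 genes were called with 2-fold and 4034 at 0.01, against 6118. With covariates chosen after the data were seen, 2968 were called (ACTB 3' to 5') 2789 (poly-A spike-ins) and 11 (18S), and the difference of effects was called in 1717 genes with ACTB and 19 with 18S. For miR-30 against cel-miR-67, against 734, the calls were 1113 with the stricter filter, 475 with plain probe sets, 443 with only the arm's 6 arrays, 1419 with trend and robust estimation, 1220 with array weights, 218 at 0.01, 0 with 2-fold and 56 with the 18S covariate. Leaving out an array gave 297 to 542 (lowest without cel-miR-67 replicate 2, highest without miR-30 replicate 3), where limma pools the spread of the 2 arrays left with that of the other groups. The genes called in both comparisons, against 407, were 262 with no filter, 643 with the stricter filter, 267 with plain probe sets, 806 with trend and robust estimation, 748 with array weights, and 156 to 408 with an array left out. The correlation of effects stayed between 0.097 and 0.15.

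BCL9 in shBCL9 was -0.17 with array weights, -0.075 after quantile normalization and -0.21 to -0.094 with an array left out, and its single probe set gives no separate value per probe set. With an estimated correlation, 0 lists were called in shBCL9 and 4 in the arrays labelled miR-30. In shBCL9, plain probe sets turned the sign of BTRC (0.20), CTBP1 (0.041), TNIP1 (0.20), SDHC (-0.82), ARSB (0.064), BIRC5 (-0.17), APC (-0.15) and SOCS3 (-1.85), and in the arrays labelled miR-30 that of SQSTM1 (0.0035). The mean of probe sets turned the sign in shBCL9 of SDHC (-0.10), PSMB2 (-0.0069), LEF1 (0.025), APC (-0.024) and SOCS3 (-0.66). The GAPDH 3' to 5' difference was -0.026 after quantile normalization, against -0.005. With the replicate block, 6340, 589 and 3996 genes were called, and the pairing check gave correlations of arrays of the same number between 0.0497 and 0.10 in the hairpin arm and 0.0913 and 0.226 in the other, where not every array correlated best with its own number. Lists were not run with array weights, median centring, the stricter filter, plain probe sets or the trend model. Under the alternatives run, no called list was reversed, while medians of some uncalled lists turned in sign. The miR-30 site test was not run, because sequences of untranslated regions were not used here.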

Other observations

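Of 11 gene families chosen after the values were seen, only the Fc receptor-like genes were called in shBCL9 with an estimated correlation. In shBCL9 all 5 measured Fc receptor-like genes of B lineage cells fell, FCRL2 (-2.37), FCRL5 (-2.04), FCRL3 (-1.56, near background in shBCL9 at 4.82), FCRLA (-1.35) and FCRLB (-0.54), with a camera adjusted p of 1.84e-06 over the families (adjusted p = 0.027 with an estimated correlation). Of 38 histone genes, 19 fell, including H2AC6 (-2.08), H2BC5 (-1.29) and H4C8 (-1.14), and 4 rose (adjusted p = 0.0525 with an estimated correlation). Of 10 BEX and TCEAL genes, 6 fell, including BEX4 (-2.04), BEX3 (-1.78) and TCEAL9 (-1.70), and TCEAL4 rose (0.29), with adjusted p = 0.095 with an estimated correlation. Of 17 intraflagellar transport genes, which build cilia, 11 fell, including IFT74 (-0.91), IFT80 (-0.71) and IFT46 (-0.60), and none rose (adjusted p = 0.095 with an estimated correlation). Zinc finger genes fell in 165 of 391 cases and rose in 34 (adjusted p = 0.0609 with an estimated correlation). E2F genes and guanylate binding proteins had adjusted p = 0.0525 with an estimated correlation. Kinesins (camera adjusted p = 0.628), mitochondrial ribosomal proteins (0.236), centromere proteins (0.236) and Notch targets (0.961) were not called.

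In the arrays labelled miR-30, centromere protein genes rose in 8 of 20 cases, including CENPF (0.65), CENPE (0.57) and CENPA (0.52), with a camera adjusted p of 2.66e-09 (adjusted p = 0.00899 with an estimated correlation). E2F8 (0.92) and E2F7 (0.68; another probe set measured -0.03) rose of 8 E2F genes (adjusted p = 0.00899 with an estimated correlation). Kinesin genes rose in 9 of 39 cases with a median of 0.02 (adjusted p = 0.016 with an estimated correlation). Histone genes fell in 10 of 38 cases and rose in 2 (camera adjusted p = 0.00264; adjusted p = 0.118 with an estimated correlation). The other 7 families were not called with an estimated correlation (adjusted p = 0.211 to 0.955). With the preset correlation, camera called mitochondrial ribosomal proteins (median -0.096, adjusted p = 4.27e-05) and BEX and TCEAL genes (median -0.197, adjusted p = 0.00192) lower. Both calls were lost with an estimated correlation (adjusted p = 0.522 and 0.211). These families share members with the lists in part and are hypotheses found and tested on the same data.

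The arms also differed between their controls. MACROD2 measured 10.87 in shGFP, 6.21 with cel-miR-67 and 6.15 in the arrays labelled miR-30, and was 14.6-fold lower in shBCL9, so shGFP stood apart, whereas CCND2 measured 6.10 in shBCL9 and 10.70, 11.62 and 11.64 in the other groups. FAM43A was low in shGFP (6.84) and 10.11, 9.17 and 8.91 elsewhere. Of the 280 genes changed 2-fold, 169 lay nearer to shGFP and 111 nearer to shBCL9 in the cel-miR-67 arrays. A second hairpin against BCL9 and a control hairpin in another culture, with BCL9 measured by PCR, would test which of these changes follow BCL9.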
